A study of Drosophila melanogaster with 14 samples.

How the data were processed

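RNA was sequenced from thoraces, which hold the flight muscle, and from carcasses, which hold the fat body, of 10 day old Drosophila melanogaster females fed for 20 h on 2.5% sucrose or on sucrose with the gut pathogen Pseudomonas entomophila at an OD600 of 50 to 60. Per the labels' protocols, 8 thoraces or 8 carcasses were pooled per sample, RNA was taken with Trizol, and stranded total RNA libraries were made. The 14 libraries cover 2 tissues and 7 conditions, with 1 library per condition and tissue. Whether the tissues came from the same flies, and whether the conditions came from separate cultures, is not given in the sources used here. The sample names give infected Dro-GFP libraries a different infection code from infected control and Relish RNAi libraries. What the code stands for is not given. A response of infected Dro-GFP libraries alone therefore cannot be assigned to the line rather than to what the code marks.

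The deposited table gives 13577 genes in 14 columns, all of them used, as normalized expression values whose log base the authors did not state in the labels or the file header. The aligner, the counting tool, the genome build and the scaling of the libraries are not given in the sources used here. The values were checked for their scale: each gene averaged 0 over the 14 libraries, with the largest absolute gene mean below 1e-12, so the table holds a log scale centred for each gene. Differences are therefore given in log units and never as folds. Read counts and depth are unknown, no level of expression can be read from the table, and 729 genes had a profile identical to 6 decimals to that of another gene, with a median range over the libraries of 0.105 against 1.037 for all genes. For some of the genes named here, near-identical copies or overlapping genes could share reads, which is said for many but not all of them.

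Groups were taken from the labels. The lines were the control (the flight muscle driver Act88F-Gal4 crossed to w1118), Relish RNAi under the same driver, and a drosocin-GFP reporter called Dro-GFP. Every test used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all 13577 genes, threshold 0.05). Infection in each tissue, the difference of the tissues in it, and Relish RNAi in each tissue came from a model with an intercept per tissue and line and an infection term per tissue. Dro-GFP positive against negative, the difference of infection between the lines, and thorax against carcass came from a model of 7 conditions plus tissue, whose error is the spread of a condition's value between the tissues. The labels give both tissues of a condition the same sample suffix, so they may be parts of 1 pool of flies, and the errors and p of these contrasts then leave out the variation between pools. Both models had 8 coefficients and 6 residual degrees of freedom. Values of 1 library against 1 have no replicate check and carry no p.

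The tests, the alternatives, the rule for named genes and 28 gene lists were fixed before the data were examined. After the values were seen, 6 contrasts were added in the model of 7 conditions plus tissue: infection over both tissues (3 lines weighted equally), infection in the control line, in the Relish RNAi line and in each group of infected Dro-GFP flies, and Relish RNAi over both tissues. The planned pseudocount, filter on low values, mean trend of eBayes and matching on mean expression could not be applied to centred values; the trend was left out, and random lists were matched on the SD over libraries outside the comparison.

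The lists were IMD antimicrobial peptides, the IMD pathway and its regulators, Toll effectors, the Toll pathway, JAK/STAT and Turandot genes, JNK and wound response, heat shock and oxidative stress, glutamate and proline metabolism, the TCA cycle, oxidative phosphorylation, glycolysis and lactate, trehalose, glycogen and gluconeogenesis, lipid synthesis and storage, lipolysis and beta-oxidation, lipoproteins and lipid transport, insulin, FoxO and adipokinetic signalling, one-carbon, folate and methionine metabolism, proteasome and autophagy, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, flight and skeletal muscle structure, and markers of fat body, oenocytes, haemocytes, gut, ovary and germline, neurons, and Malpighian tubule with trachea and spermatheca. Of the 630 members, fixed by name or, for ribosomal proteins, by a pattern of their symbols, 13 were not found and 1 repeated another member of its list, which left 616. Of the members found, 40 were matched through an older symbol. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the residuals, each adjusted over the 28 lists. Members were also counted with p adjusted over the list alone. In comparisons of 1 library against 1, a list's median was placed among those of 10000 random lists of the same size matched in 20 bins; this percentile describes these libraries only.

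Named genes were the 10 highest and the 10 lowest among those past the threshold with the same sign in every library pair of the contrast, fewer where fewer passed, together with Rel, Dro, Act88F, Gdh and members of the fixed lists. In values of 1 library against 1, they were the 10 highest and the 10 lowest differences. Genes known only by a CG or CR number were mostly counted. A gene outside this rule is said to have been chosen after its values were seen.

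The alternatives were median-of-ratios scaling and quantile normalization within each tissue, robust eBayes, a threshold of 0.1, each library left out in turn, fits on part of the libraries or without the line term, a filter on genes with a range under 0.5 (2246 genes), and a fit without both carcass libraries of the Relish RNAi line. The fits were tested on simulated tables of 13577 genes in which 200 genes were changed by 1, 2 or 4 log units. Of the changes of 1 log unit, 82.1% were recovered for infection in thorax, 74.6% for infection in carcass, 59.7% for Dro-GFP positive against negative and 38.8% for the difference of infection between the lines. Changes of 4 log units were recovered in at least 97% of cases in these comparisons. These changes were placed on genes drawn at random, with independent noise. The measured antimicrobial peptides, at medians of 4.18 and 4.43 for infection in thorax and carcass, did not pass over all genes, so the simulation does not describe the power for them. Lists and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.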

Results

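Gene expression was measured in muscle-rich thoraces and fat-body-rich carcasses of female flies after feeding on sucrose or on Pseudomonas entomophila, in order to describe how these tissues respond to an infection of the gut. The 14 libraries comprised, in each of 2 tissues, control flies fed sucrose or bacteria, flies with Relish RNAi under a flight muscle driver fed sucrose or bacteria, and Dro-GFP reporter flies fed sucrose, infected with GFP detected (GFP-positive) or infected without GFP (GFP-negative). Each condition had 1 library per tissue. Values are differences in log units of unknown base, and the depth of the libraries is unknown. Errors after ± are standard errors from limma.

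Infection raised the antimicrobial peptides of the IMD pathway, the immune pathway that answers Gram-negative bacteria. All 13 measured peptides were higher in each of the 8 infected libraries than in the sucrose library of the same line and tissue. Over both tissues and 3 lines, DptA, a diptericin, rose by 5.41 ± 0.28 (adjusted p = 0.000104) and Dro, drosocin, by 4.99 ± 0.31 (adjusted p = 0.000214). The gene edin, a secreted peptide induced by infection, rose by 4.95 ± 0.18 (adjusted p = 4.62e-05) and DptB by 4.32 ± 0.19 (adjusted p = 4.89e-05). CecA2 rose by 4.67 ± 0.25 and AttB by 4.61 ± 0.26, although CecA1 and CecA2, and AttA and AttB, are near-identical copies whose reads could be shared. The whole list rose, 13 of 13 over all genes and 13 of 13 adjusted over the list alone, with a median of 4.32 (camera adjusted p = 8.9e-43; adjusted p = 0.0153 with an estimated correlation). This contrast over both tissues was added after the values were seen.

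**Figure D1:**
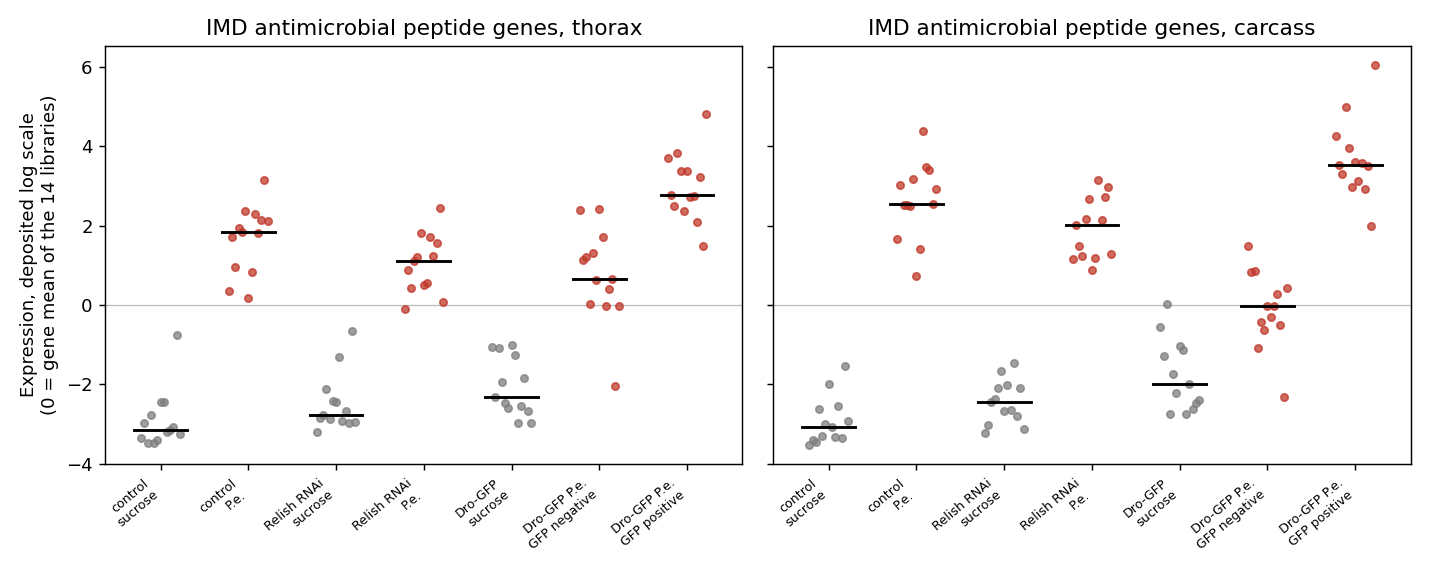
Values of the 13 IMD antimicrobial peptides in each library, in log units centred per gene over the 14 libraries, by tissue and condition. The sucrose libraries had list means from −2.94 to −1.77 and the infected libraries from −0.11 to 3.67.

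Part of the IMD pathway's own components and regulators rose with its peptides. Rel, the NF-kappaB factor of the pathway, rose by 0.94 ± 0.06 (adjusted p = 0.000214), as did the receptor gene PGRP-LC (0.84) and its relative PGRP-LF (0.96). The amidases that break down peptidoglycan and so restrain the pathway rose more, PGRP-SC2 by 3.94, PGRP-LB by 2.53 and PGRP-SC1b by 2.18. In all, 8 of 21 members rose over all genes and 10 adjusted over the list alone, including pirk, an inhibitor of the receptors (1.45). The list median was 0.26 (camera adjusted p = 1.11e-12; adjusted p = 0.015 with an estimated correlation). Among Toll effectors, short peptides induced through the Toll receptor, 15 of 17 rose over all genes and 15 adjusted over the list alone. Their median was 1.69 (camera adjusted p = 4.24e-38; adjusted p = 0.0153 with an estimated correlation). They included the antifungal peptides Drs (2.73) and Mtk (2.75), the bomanin IM1 (2.17) and CR44404, known as IBIN, a short immune-induced transcript (4.47 ± 0.22; adjusted p = 7.9e-05). In the Toll pathway itself, 4 of 18 members rose over all genes and 10 adjusted over the list alone, among them spz, the Toll ligand (0.65), and Hayan, a protease of the melanization cascade (1.21). The Toll pathway list had a camera adjusted p of 2.71e-09, but an adjusted p = 0.111 with an estimated correlation.

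Genes of JAK/STAT signalling, which answers stress and tissue damage, also rose, 5 of 16 over all genes and 11 adjusted over the list alone. Their median was 0.77 (camera adjusted p = 1.04e-11; adjusted p = 0.015 with an estimated correlation). The receptor dome rose by 0.45, the feedback inhibitor Socs36E by 0.80, and the thioester proteins Tep1 and Tep2 by 1.56 each. Outside the immune lists, Tsf1, an iron-binding transferrin, rose by 1.88 (adjusted p = 0.00398) and Gadd45, a stress gene of the JNK list, by 1.22. The glutathione transferase GstE1 rose by 1.73, and the amylases Amy-p and Amy-d, near-identical copies, by 1.79 and 0.98. Genes that fell included Jabba, a lipid droplet protein, by 0.62 ± 0.10 (adjusted p = 0.0261), and the cytochrome P450 Cyp4ac2, by 0.55 ± 0.08 (adjusted p = 0.0182). The Notch target E(spl)m2-BFM fell by 0.61 ± 0.11 (adjusted p = 0.0407), and Shmt, a one-carbon enzyme, by 0.36 (adjusted p = 0.0383). For one-carbon, folate and methionine metabolism, 3 members rose and 1 fell adjusted over the list alone. Among them were Gnmt at 1.96 and Sardh at 1.07 (camera adjusted p = 0.0329; adjusted p = 0.55 with an estimated correlation).

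In all, 184 genes rose and 30 fell in limma over both tissues, while the planned fits within each tissue passed 0. The error here is the spread between the tissues of a condition, which may come from 1 pool of flies. It leaves out variation between pools and differences in response between lines. With least-squares weights, 5 of 34 splits of the conditions, the real one included, passed as many genes, so chance was not excluded for this count. The count was 90 without both carcass libraries of the Relish RNAi line, which held eggshell transcripts. Leaving out 1 thorax library gave 127 without control sucrose, 103 without Relish RNAi sucrose, 134 without infected control and 126 without Dro-GFP sucrose. Leaving out 1 carcass library gave 114, 109, 141 and 121 for the same conditions and 139 without the GFP-negative library. Ovary and germline markers were lower with infection, with 1 of 21 above 0 and a median of −0.44 (camera adjusted p = 0.00784; adjusted p = 0.55 with an estimated correlation). Control flies did not share this in thorax, with a median of 0.36 (17 of 21 higher), and showed little of it in carcass, with a median of −0.133 (12 of 21 lower) and a list mean of −0.18 on both feeds, and 0 members were below 0 in all 8 infected libraries. Camera also called cytosolic ribosomal proteins (median −0.18), glycolysis (−0.17) and lipid synthesis (−0.12) lower and gut markers (0.06) higher. For these lists, adjusted p = 0.55 with an estimated correlation. In GFP-negative carcasses, glycolysis and lipid synthesis instead lay above sucrose (0.227 and 0.173). Heat shock genes had 23 of 27 above 0 (camera adjusted p = 8.24e-05; adjusted p = 0.34 with an estimated correlation), carried chiefly by the Dro-GFP libraries. Their median difference was −0.174 in control and 0.025 in Relish RNAi thoraces, and 0.064 and −0.069 in those carcasses. By list mean, however, infected carcasses were higher in control flies too, −0.71 against −1.104, and in Relish RNAi flies, −0.573 against −0.737. Dro-GFP carcasses stood at −0.323 on sucrose, 1.282 in GFP-negative and 0.285 in GFP-positive flies.

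Within the thorax, the planned fit showed the same peptides far above sucrose, with a median of 4.18 for the IMD antimicrobial peptides and 1.6 for Toll effectors. Even so, 0 genes passed over all genes in limma, with 830 at an unadjusted p under 0.05 against 679 expected at random. Adjusted over the list alone, 13 of 13 antimicrobial peptides, 15 of 17 Toll effectors, 8 of 21 IMD pathway members, 5 of 18 Toll pathway members and 2 of 16 JAK/STAT genes rose. Camera called these 5 lists higher, with adjusted p from 6.47e-29 to 6.81e-08. For the peptides adjusted p = 0.144 with an estimated correlation, for the IMD pathway adjusted p = 0.227, and for the other lists adjusted p = 0.121. Genes whose 4 infected thorax libraries all lay above the 3 sucrose libraries numbered 638, and 418 lay below, where chance gives 2.86%, or 388 genes, each. Among them were 12 of 13 antimicrobial peptides and 15 of 17 Toll effectors.

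Cytosolic ribosomal proteins and proteasome and autophagy genes were slightly lower in infected thoraces of every line, and other housekeeping lists in part of the lines. Of the proteasome and autophagy genes, 16 of 27 were below 0 in all 4 infected thoraces. Their list mean was barely lower in GFP-negative thoraces, −0.163 against −0.146 on sucrose. Cytosolic ribosomal proteins had a median of −0.14 with 3 of 90 above 0 (camera adjusted p = 9.43e-12; adjusted p = 0.759 with an estimated correlation). Of the 90, 55 had all infected thorax libraries below all sucrose thorax libraries, where chance gives 2.86% for a gene taken alone. Genes that move together can reach such a count through a single shift, and in carcass the count was 5 of 90. Proteasome and autophagy genes had a median of −0.14 (camera adjusted p = 1.65e-05; adjusted p = 0.665 with an estimated correlation). Oxidative phosphorylation stood at −0.08 (camera adjusted p = 0.00557) and mitochondrial ribosomal proteins at −0.07 (camera adjusted p = 0.0293), with adjusted p = 0.916 with an estimated correlation for both. Mitochondrial ribosomal proteins were not lower in the infected Relish RNAi thorax (41 of 72 higher) or the GFP-negative thorax (40 of 72 higher), and oxidative phosphorylation was higher in 33 of 36 in the former. Glycolysis stood at −0.12 (camera adjusted p = 0.0385; adjusted p = 0.883 with an estimated correlation). Heat shock and oxidative stress genes had 24 of 27 above 0 and a median of 0.31 (camera adjusted p = 0.000155; adjusted p = 0.347 with an estimated correlation). This came from the Dro-GFP libraries, in which line and infection code cannot be separated. Their list mean was −0.2 on sucrose and 1.019 and 1.003 on infection. It was −0.03 and −0.147 in control and 0.117 and 0.119 in Relish RNAi flies. One-carbon genes had a median of 0.12 (camera adjusted p = 0.00258; adjusted p = 0.28 with an estimated correlation). None of the members of these lists passed adjusted over the list alone. Camera called no other list in thorax: medians were 0.06 for JNK, −0.03 for glutamate and proline metabolism, −0.04 for the TCA cycle, −0.06 for trehalose and glycogen and −0.11 for lipid synthesis. They were −0.06 for lipolysis, −0.04 for lipoproteins, 0.09 for insulin signalling and −0.05 for muscle structure. Among markers they were −0.13 for oenocytes, −0.09 for haemocytes, −0.11 for ovary, −0.08 for neurons and 0.03 for Malpighian tubule markers. Fat body markers (median −0.08, mean 0.03) and gut markers (median −0.004, mean 0.14) had a median and a mean of opposite sign.

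In the carcass, the antimicrobial peptides stood at a median of 4.43, Toll effectors at 1.49 and JAK/STAT genes at 0.97. Adjusted over the list alone, 13 of 13 peptides, 14 of 17 Toll effectors, 9 of 16 JAK/STAT genes, 7 of 21 IMD pathway members and 3 of 18 Toll pathway members rose. Camera adjusted p ran from 8.15e-18 to 6e-05 for these 5 lists. For the IMD pathway adjusted p = 0.345 with an estimated correlation, and for the others adjusted p = 0.287 with an estimated correlation. Over all genes, 0 passed in limma, with 1702 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0652. The count was 169 (53 higher and 116 lower) without the control sucrose library or without the infected control library of the carcass. Either omission takes the control line out of this estimate, so both give the same fit. Without the carcass GFP-negative library the count was 53 (39 higher and 14 lower). Groups that did not overlap numbered 455 genes above and 538 below, where chance gives 2.86%, or 388 genes, for each.

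Ovary and germline markers were lower in infected carcasses, with 0 of 21 above 0 and 1 member lower adjusted over the list alone. Their median was −0.80 (camera adjusted p = 6.1e-06; adjusted p = 0.287 with an estimated correlation). The difference came from the Relish RNAi line, with list means of 2.115 on sucrose and 0.97 on infection, and from Dro-GFP flies, at 0.783 on sucrose and −0.71 and −0.603 in GFP-negative and GFP-positive flies. Both control carcasses were at −0.18. Only 4 of 21 members were below 0 in all 4 infected carcasses. Cytosolic ribosomal proteins had a median of −0.23 with 3 of 90 above 0 (camera adjusted p = 4.09e-22; adjusted p = 0.432 with an estimated correlation). Heat shock and oxidative stress genes had a median of 0.49, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000333; adjusted p = 0.345 with an estimated correlation). In control carcasses 15 of 27 and in Relish RNAi carcasses 13 of 27 were higher. Lipoproteins had a median of 0.15 (camera adjusted p = 0.0265; adjusted p = 0.339 with an estimated correlation) and gut markers 0.10 (camera adjusted p = 0.0265; adjusted p = 0.641 with an estimated correlation), each with 1 member higher adjusted over the list alone. The infected Relish RNAi carcass stood apart in gut markers, with a list mean of 0.717 against −0.259 on sucrose; the means were −0.271 and −0.249 in control and −0.026, −0.07 and −0.091 in Dro-GFP flies. The list mean of lipoproteins was not higher in infected control flies, 0.131 against 0.18. Mitochondrial ribosomal proteins had a median of −0.06 (camera adjusted p = 0.0196; adjusted p = 0.828 with an estimated correlation), but 49 of 72 were higher in the infected control carcass.

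The response of the carcass was not shown to differ from that of the thorax for any gene: 0 passed in limma, with 651 at an unadjusted p under 0.05. The antimicrobial peptides differed by a median of 0.55 (camera adjusted p = 0.72), and Rel differed by 0.15 ± 0.33 (adjusted p = 1). Camera called the response of ovary markers lower in carcass (median −0.82), that of cytosolic ribosomal proteins lower (median −0.09), and those of haemocyte and neuron markers higher (0.22 each). Their adjusted p were 0.000445, 0.000128, 0.0267 and 0.0316. All 4 calls were lost, adjusted p = 0.979 with an estimated correlation.

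**Figure D2:**
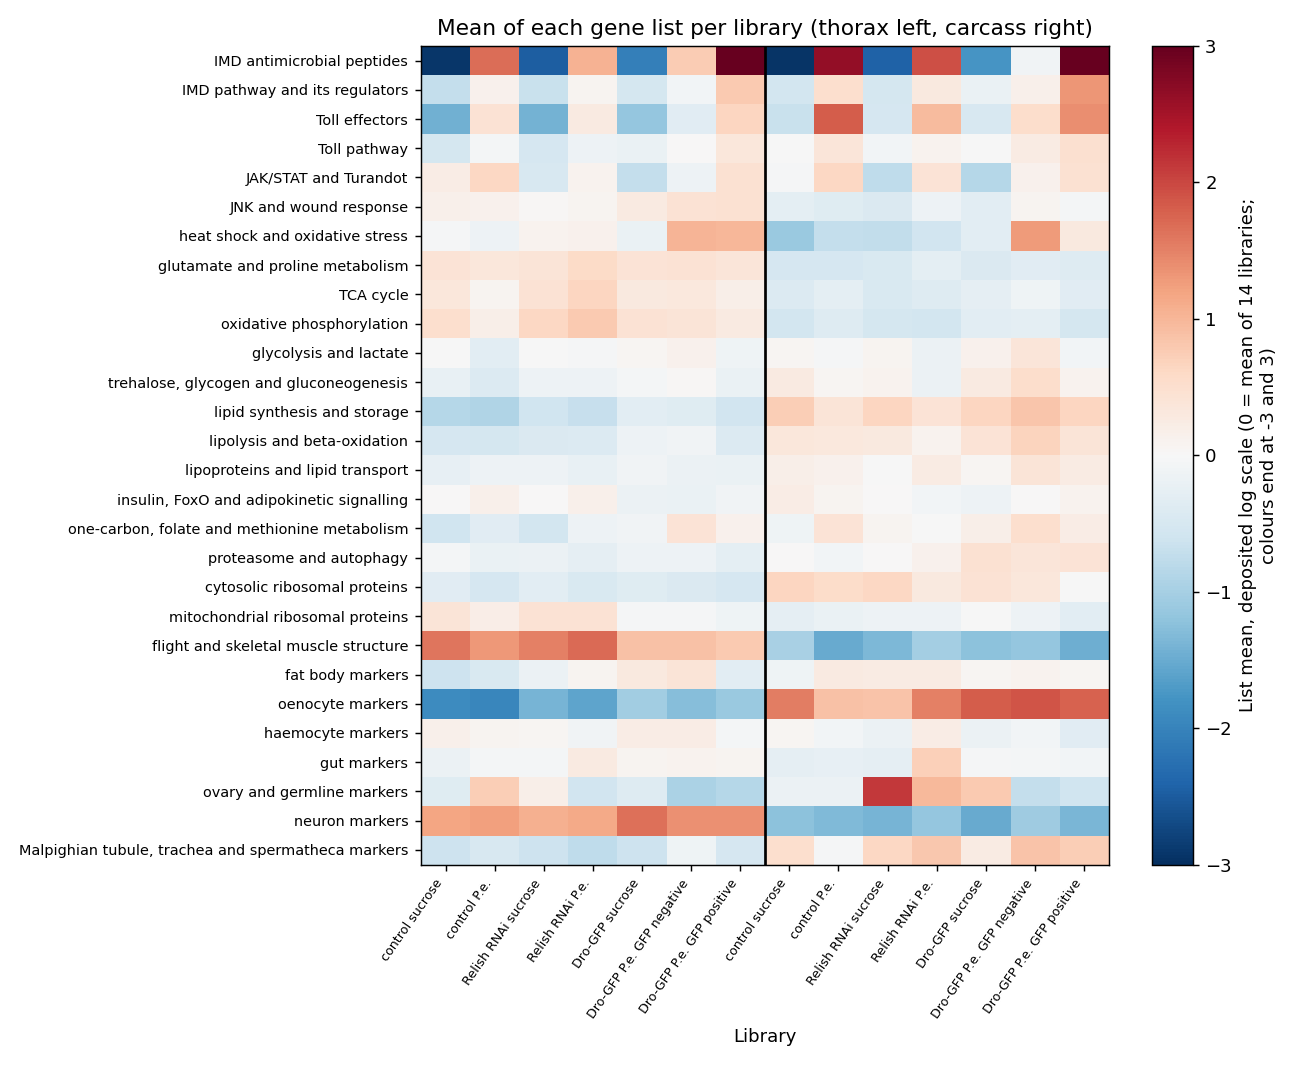
Mean value of each of the 28 gene lists in each of the 14 libraries, in log units centred per gene. The means of the antimicrobial peptides, the IMD pathway and Toll effectors separate sucrose from infected libraries, and those of muscle structure and lipid lists separate the tissues.

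Infection raised immune genes in control flies taken alone. Over both tissues, DptA rose by 6.59 ± 0.51 (adjusted p = 0.00177), CR44404 by 6.15 ± 0.40 (adjusted p = 0.00106) and Dro by 6.0 ± 0.57 (adjusted p = 0.00426). CecA2 rose by 5.97 ± 0.46 and edin by 5.62 ± 0.32. Of the antimicrobial peptides, 12 of 13 rose over all genes and 13 adjusted over the list alone (median 5.50; adjusted p = 0.0156 with an estimated correlation). Toll effectors gave 12 of 17, or 15 adjusted over the list alone, and the IMD pathway 4 of 21, or 7, both with adjusted p = 0.0156 with an estimated correlation. JAK/STAT genes gave 1 of 16, or 3 (adjusted p = 0.0735 with an estimated correlation), and the Toll pathway 1 of 18, or 5 (adjusted p = 0.165 with an estimated correlation). Rel rose by 1.08 (adjusted p = 0.00476), Tep2 by 2.25, Tsf1 by 2.53 and Hayan by 1.53, while dpp, a BMP ligand, fell by 0.66 ± 0.10 (adjusted p = 0.042). Muscle structure genes were all below 0, 0 of 27 above, with a median of −0.38 (camera adjusted p = 1.83e-10; adjusted p = 0.439 with an estimated correlation). This contrast was added after the values were seen and gave 66 genes higher and 2 lower. The count was 34 without the thorax sucrose library of this line, 24 without its carcass sucrose library, and 29 without both Relish RNAi carcass libraries.

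In single libraries without a replicate check, the infected control thorax exceeded its sucrose library by a median of 4.72 in the antimicrobial peptides (13 of 13 higher), and the carcass by 5.85. Genes of energy metabolism and muscle structure lay lower in the infected control thorax. Other metabolic lists were mixed, with medians of −0.145 for glutamate and proline metabolism, −0.105 for trehalose and glycogen and −0.073 for lipolysis. Lipid synthesis stood at −0.035, one-carbon genes at 0.098 and lipoproteins at 0.112. The median was −0.35 for oxidative phosphorylation (0 of 36 higher, percentile 0.0) and −0.28 for the TCA cycle (1 of 20 higher). It was −0.34 for glycolysis (0 of 13 higher) and −0.35 for muscle structure (3 of 27 higher). In the control carcass, oxidative phosphorylation had a median of 0.17 (30 of 36 higher, percentile 99.89) and muscle structure −0.58 (1 of 27 higher). There, oenocyte markers had a median of −0.68 (0 of 9 higher) and one-carbon genes 0.34 (10 of 13 higher). Ovary markers had a median of 0.36 in the infected control thorax (17 of 21 higher). That library held the mucin-like Mur11Da at 6.32 above sucrose, the largest named difference of the pair apart from 3 genes known only by CG numbers. Muc68D, another mucin, was 6.72 lower in the infected than in the sucrose control carcass (−6.72).

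Rel, the target of the RNAi, was lower in the infected Relish RNAi libraries than in the infected control libraries and alike in sucrose. In thorax, Rel stood at −0.75 in control sucrose, −0.83 in Relish RNAi sucrose, 0.20 in infected control and −0.36 in infected Relish RNAi. In carcass, the values were −0.48, −0.50, 0.74 and −0.09 in the same order. The difference between the lines was thus −0.07 and −0.56 in thorax, and −0.02 and −0.83 in carcass, for sucrose and infection. Averaged over both feeds, limma gave −0.32 ± 0.30 in thorax (adjusted p = 0.999) and −0.42 ± 0.30 in carcass (adjusted p = 0.801). In Dro-GFP flies, Rel stood at −0.59 in sucrose, 0.41 in GFP-negative and 0.80 in GFP-positive thoraces, and at −0.46, 0.71 and 1.20 in carcasses. Whether reads from the hairpin count toward Rel is not given in the sources used here.

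**Figure D3:**
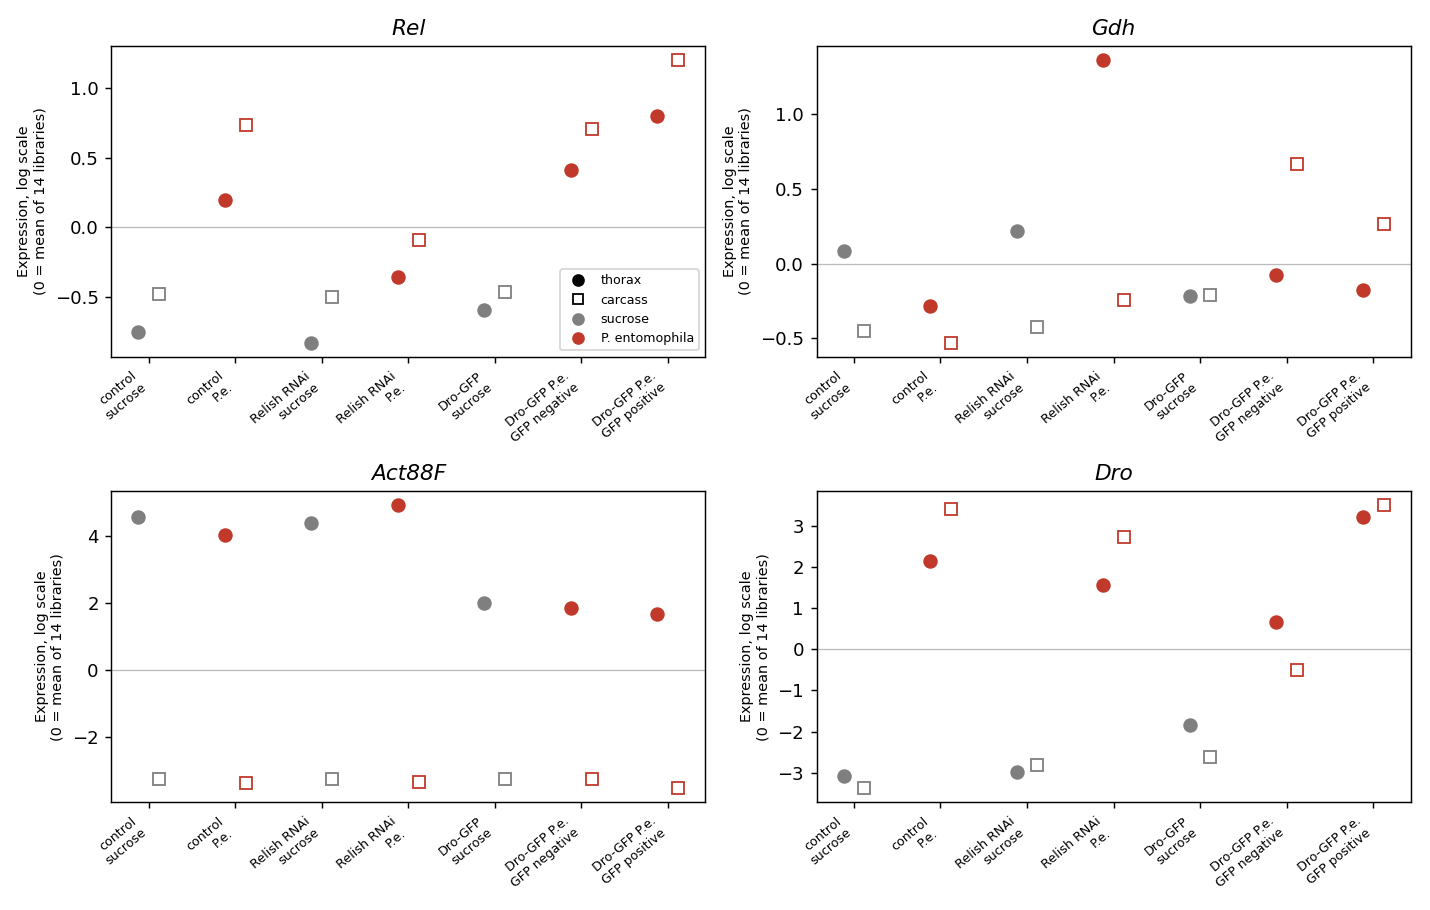
Values of Rel, Dro, Act88F and Gdh in each of the 14 libraries, in log units centred per gene. Rel was at −0.36 in the infected Relish RNAi thorax against 0.20 in the infected control thorax, and Gdh at 1.36 against −0.28.

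In the thorax, where the driver acts, genes of mitochondrial energy metabolism were higher in the Relish RNAi line on average over the feeds, chiefly through the infected libraries. List means of oxidative phosphorylation were 0.62 in Relish RNAi against 0.51 in control flies on sucrose, and 0.79 against 0.175 on infection, and those of the TCA cycle 0.44 against 0.34 and 0.65 against 0.08. All 36 oxidative phosphorylation genes were above 0, with a median of 0.36 (camera adjusted p = 7.34e-26; adjusted p = 0.429 with an estimated correlation). So were 19 of 20 TCA cycle genes, with a median of 0.33 and 7 members higher adjusted over the list alone (camera adjusted p = 2.65e-14; adjusted p = 0.429 with an estimated correlation). Mitochondrial ribosomal proteins had a median of 0.14 (camera adjusted p = 3.28e-08; adjusted p = 0.78 with an estimated correlation). JAK/STAT genes were lower, with a median of −0.36 and 3 members lower adjusted over the list alone (camera adjusted p = 3.22e-05; adjusted p = 0.429 with an estimated correlation). Muscle structure genes had a median of 0.19, with 1 member lower adjusted over the list alone (camera adjusted p = 0.00436; adjusted p = 0.796 with an estimated correlation). Their list mean was lower than in control flies on sucrose, 1.51 against 1.61, and higher on infection, 1.70 against 1.31. Ovary and germline markers differed between the infected thoraces too, with list means of 0.746 in control and −0.572 in Relish RNAi flies, so these libraries differed in transcripts of another tissue. Fat body markers moved along with the metabolic genes, with a median of 0.28 (camera adjusted p = 0.00182; adjusted p = 0.429 with an estimated correlation). The antimicrobial peptides had a median of −0.09 (camera adjusted p = 0.736).

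Camera also called proteasome genes lower in that contrast (median −0.11, adjusted p = 1.18e-05; adjusted p = 0.78 with an estimated correlation). It called 4 lists higher. Glycolysis stood at 0.14, trehalose and glycogen at 0.11 and lipid synthesis at 0.16 (adjusted p = 0.796 with an estimated correlation for each). Oenocyte markers stood at 0.18 (adjusted p = 0.78 with an estimated correlation). In limma, 1 gene passed, the noncoding CR43704, which was higher by 2.14 ± 0.15 (adjusted p = 0.00942), with 634 genes at an unadjusted p under 0.05. The count was 8 without the thorax control sucrose library and 0 without the infected control thorax, without the GFP-negative thorax, in the thorax libraries alone, or without the Dro-GFP libraries.

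In the carcass, eggshell genes were higher in the Relish RNAi line. Vm26Aa, Vm26Ab and Vm34Ca, vitelline membrane proteins laid down by ovarian follicle cells, were higher by 7.14 ± 0.67 (adjusted p = 0.0141), 6.64 ± 0.31 (adjusted p = 0.000442) and 6.47 ± 0.70 (adjusted p = 0.0323). The rhomboid protease stet, which acts in the germline, was higher by 2.17 ± 0.19 (adjusted p = 0.0141). Of the ovary and germline markers, 3 of 21 rose over all genes and 5 adjusted over the list alone. Their median was 0.63, with 17 above 0 (camera adjusted p = 4.45e-08; adjusted p = 0.717 with an estimated correlation). Gut markers had a median of 0.34 (camera adjusted p = 0.00249; adjusted p = 0.846 with an estimated correlation), through the infected pair, with list means of 0.717 against −0.249. Toll effectors had a median of −0.35 with 2 of 17 above 0 (camera adjusted p = 0.000917; adjusted p = 0.852 with an estimated correlation). Their list mean was higher than in control flies on sucrose, −0.507 against −0.663, and lower on infection, 0.951 against 1.818. Insulin signalling stood at −0.23 (camera adjusted p = 0.00812; adjusted p = 0.846 with an estimated correlation) and cytosolic ribosomal proteins at −0.19 (camera adjusted p = 3.16e-11; adjusted p = 0.852 with an estimated correlation).

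Of the other lists in the carcass, camera called proteasome genes at 0.14 and lipolysis at −0.19 (adjusted p = 0.852 with an estimated correlation for both). It also called the Toll pathway at −0.20, and JAK/STAT genes at −0.17 with 4 members lower adjusted over the list alone (adjusted p = 0.846 with an estimated correlation for both). Mitochondrial ribosomal proteins stood at 0.08 (adjusted p = 0.943 with an estimated correlation). In limma, 7 genes were higher and 0 lower, with 1092 at an unadjusted p under 0.05. The rest were CG12398, CG10445 and CG13311. The 7 fell to 4 with quantile normalization and to 0 in the carcass libraries alone or without the Dro-GFP libraries. Leaving out 1 thorax library gave 1 without control sucrose, 1 without infected control, 4 without Dro-GFP sucrose, 2 without GFP-negative and 4 without GFP-positive. Leaving out 1 carcass library gave 2 without control sucrose, 53 without Relish RNAi sucrose, 75 without infected control and 14 without infected Relish RNAi.

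Over both tissues, NimC1, a phagocytosis receptor of haemocytes, was lower in the Relish RNAi line, at −1.58 ± 0.13 (adjusted p = 0.0175), with the same sign in all 4 pairs. The odorant receptor Or49b was also lower, at −0.97 ± 0.08 (adjusted p = 0.0175). Haemocyte markers as a list had a median of 0.04 (camera adjusted p = 0.659), so NimC1 did not move with its list. Gut markers gave 0 over all genes and 4 higher adjusted over the list alone (camera adjusted p = 2.47e-05, and 0.735 with an estimated correlation). The infected carcasses stood furthest apart in this list, with means of 0.717 in Relish RNAi and −0.249 in control flies. JAK/STAT genes gave 6 lower adjusted over the list alone (camera adjusted p = 2.47e-05; adjusted p = 0.232 with an estimated correlation). This contrast was added after the values were seen and gave these 2 genes only. Without the thorax Relish RNAi sucrose library the count was 4, without the infected Relish RNAi thorax 10, without the infected control carcass 10 and without the infected Relish RNAi carcass 1. It was 0 without any of the others, namely both control thoraces, the control sucrose and Relish RNAi sucrose carcasses, and the 6 Dro-GFP libraries. Without both Relish RNAi carcass libraries the count was 1, a different gene.

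Relish RNAi flies still induced the antimicrobial peptides on infection. DptA rose by 5.21 ± 0.51 (adjusted p = 0.00987), Dro by 5.03 ± 0.57 (adjusted p = 0.0175), the amidase PGRP-SC2 by 4.39 ± 0.41 (adjusted p = 0.00885) and Def, defensin, by 4.08 ± 0.46 (adjusted p = 0.0175). Of the list, 11 of 13 rose over all genes and 13 adjusted over the list alone (median 3.76). Toll effectors gave 7 of 17, or 14 adjusted over the list alone (median 1.56), the IMD pathway 3 of 21, or 7, and JAK/STAT 0 of 16, or 9 (median 0.66). For each list adjusted p = 0.0289 with an estimated correlation. Gut digestive enzymes were higher too, with list means of 0.717 on infection and −0.259 on sucrose in carcass, beside 0.261 and −0.062 in thorax. The infected Relish RNAi carcass stood apart from every other carcass library, which ran from −0.271 to −0.026. This rise thus rests chiefly on 1 library. Of 17 gut markers, 1 rose over all genes and 6 adjusted over the list alone, including the trypsins alphaTry (1.67) and betaTry (1.78). In all, 15 lay above 0 (camera adjusted p = 1.2e-07; adjusted p = 0.158 with an estimated correlation). Muscle structure genes had 25 of 27 above 0 and a median of 0.27 (camera adjusted p = 8.08e-05; adjusted p = 0.508 with an estimated correlation), and ovary markers had a median of −0.94 (camera adjusted p = 0.000188; adjusted p = 0.418 with an estimated correlation). This added contrast gave 30 genes higher and 2 lower, but 11 in all with quantile normalization and 0 without both Relish RNAi carcass libraries. By library left out, the count was 16 and 90 without the sucrose and the infected Relish RNAi thorax, 2 and 0 without those carcasses, and 20 without either GFP-positive library.

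The lines were compared directly through the difference of their infection responses, Relish RNAi minus control. The antimicrobial peptides had a median of −1.38 with 2 of 13 above 0, and edin, at −1.88 ± 0.45, passed adjusted over the list alone (camera adjusted p = 1.03e-07; adjusted p = 0.524 with an estimated correlation). Toll effectors had 0 of 17 above 0 and a median of −0.43 (camera adjusted p = 1.03e-07; adjusted p = 0.524 with an estimated correlation). Muscle structure genes went the other way, 27 of 27 above 0 with a median of 0.63. Mlc1, a myosin light chain, at 0.83 and the Z-disc protein Mlp84B at 0.81 passed adjusted over the list alone (camera adjusted p = 8.62e-15; adjusted p = 0.524 with an estimated correlation). Mean infection differences of gut markers in Relish RNAi and control flies were 0.976 and 0.022 in carcass, and 0.324 and 0.103 in thorax. Over both tissues, gut markers had a median of 0.30, with 3 members higher adjusted over the list alone. These were alphaTry at 1.91, betaTry at 1.97 and yip7 at 1.06 (camera adjusted p = 0.00279; adjusted p = 0.524 with an estimated correlation). Ovary markers had a median of −1.24 (camera adjusted p = 2.32e-05; adjusted p = 0.524 with an estimated correlation).

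Energy genes lay on the same side as the muscle genes over both tissues, chiefly through the thorax. The TCA cycle had a median of 0.25 (camera adjusted p = 0.0378; adjusted p = 0.833 with an estimated correlation), and oxidative phosphorylation 0.17 with 35 of 36 above 0 (camera adjusted p = 0.0439; adjusted p = 0.896 with an estimated correlation). In carcass, the median infection difference of oxidative phosphorylation was 0.02 in Relish RNAi flies against 0.174 in control flies. For the TCA cycle, the medians were nearly alike there, 0.083 against 0.077, and the means were 0.079 against 0.115. Oenocyte markers had a median of 0.79 (camera adjusted p = 0.0378; adjusted p = 0.647 with an estimated correlation), and cytosolic ribosomal proteins a median of −0.10 (camera adjusted p = 0.00286; adjusted p = 0.896 with an estimated correlation). Both came from the carcass, where mean infection differences in Relish RNAi and control flies were 0.635 and −0.649 for oenocyte markers and −0.314 and −0.086 for ribosomal proteins. In thorax they had the opposite order, −0.203 and −0.089, and −0.149 and −0.172. Rel differed by −0.65 ± 0.15 (adjusted p = 0.84). Over all genes, 0 passed in limma, with 588 at an unadjusted p under 0.05 and a smallest adjusted p of 0.201. The count was 5 without the control sucrose thorax, 4 and 1 without the sucrose and infected Relish RNAi thoraces, 1 without the control sucrose carcass and 10 without the infected control carcass.

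Glutamate dehydrogenase, Gdh, which turns glutamate into alpha-ketoglutarate in mitochondria, stood out in single libraries without a replicate check. In thorax, Gdh was at 0.08 in control sucrose, −0.28 in infected control, 0.22 in Relish RNAi sucrose and 1.36 in infected Relish RNAi, so the infection difference was −0.37 in control and 1.14 in Relish RNAi flies. In carcass, those differences were −0.08 and 0.175. In thorax, a rise of this size was seen in the Relish RNAi pair only, beside 0.141 in GFP-negative and 0.042 in GFP-positive Dro-GFP flies. In carcass, a higher Gdh on infection was not particular to Relish RNAi flies. There it was 0.876 above sucrose in GFP-negative and 0.475 in GFP-positive Dro-GFP flies. Act88F, the flight muscle actin whose driver was used, differed on infection by −0.55 in control and 0.52 in Relish RNAi thoraces. In the same pair of Relish RNAi thoraces, oxidative phosphorylation had a median of 0.17 (33 of 36 higher, percentile 99.94) and the TCA cycle 0.20 (18 of 20 higher). Muscle structure stood at 0.16 (25 of 27 higher) and ovary markers at −0.58 (4 of 21 higher). In the Relish RNAi carcasses, gut markers had a median of 0.57 (17 of 17 higher, percentile 100) and oenocyte markers 1.08 (6 of 9 higher). Lipid synthesis stood at −0.40 (4 of 20 higher) and ovary markers at −0.85 (5 of 21 higher). Named genes of these pairs were DptA at 4.63 and 5.80 and Dro at 4.53 and 5.53 in thorax and carcass, with the eggshell gene Vm26Ac at −7.26 in carcass and the yolk protein receptor yl at −3.60 in thorax.

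GFP-positive flies carried more immune transcripts than infected GFP-negative flies in both tissues. The groups were split by a reporter of Dro, itself a member of the antimicrobial peptide list. Higher Dro, and higher genes induced along with it, thus follow in part from the split and are not independent results. Dro itself, on which the reporter rests, was higher by 3.28 ± 0.57 (adjusted p = 0.0588), at 3.22 against 0.65 in thorax and 3.49 against −0.51 in carcass. The peptides edin and AttD rose by 5.22 ± 0.32 (adjusted p = 0.00153) and 4.95 ± 0.49 (adjusted p = 0.00919), Def by 3.92 ± 0.46 (adjusted p = 0.0146) and DptA by 3.18 ± 0.51 (adjusted p = 0.0467). The amidases PGRP-SC1a, PGRP-SC1b and PGRP-SC2 rose by 5.92 ± 0.62 (adjusted p = 0.0118), 4.18 ± 0.33 (adjusted p = 0.00359) and 4.03 ± 0.41 (adjusted p = 0.0107), the SC1 pair being near-identical copies. Of the antimicrobial peptides, 5 of 13 rose over all genes and 13 adjusted over the list alone. Their median was 2.67 (camera adjusted p = 7.34e-24; adjusted p = 0.125 with an estimated correlation). The IMD pathway gave 4 of 21, or 6 adjusted over the list alone, and kept its call (adjusted p = 0.047 with an estimated correlation). Toll effectors gave 4 of 17, or 11 adjusted over the list alone, among them CR44404 at 3.46 ± 0.40 (adjusted p = 0.0138). For that list camera gave an adjusted p of 4.19e-12, and adjusted p = 0.24 with an estimated correlation.

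**Figure D4:**
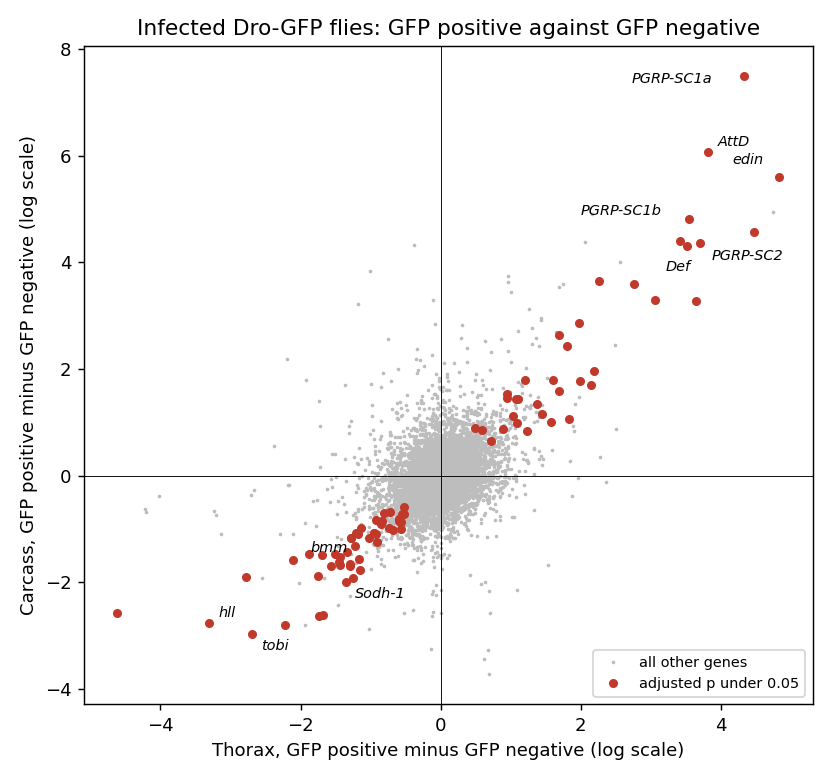
Difference of GFP-positive and GFP-negative infected flies per gene, in log units, thorax on the horizontal and carcass on the vertical axis, with genes past an adjusted p of 0.05 in red. The 36 genes that rose and the 48 that fell lie in the corners where both tissues share the sign, with edin at 5.22 and tobi at −2.83 over both tissues.

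Genes of sugar and fat use were lower in GFP-positive than in GFP-negative flies, and some of them lay above sucrose in the latter. The alpha-glucosidase tobi, a target of insulin signalling, fell by 2.83 ± 0.16 (adjusted p = 0.00153) and the acyl-CoA synthetase hll by 3.03 ± 0.23 (adjusted p = 0.00359). The sorbitol dehydrogenase Sodh-1 fell by 1.68 ± 0.20 (adjusted p = 0.0172) and Cyp12d1-p, a mitochondrial cytochrome P450, by 1.85 ± 0.21 (adjusted p = 0.0138). The triglyceride lipase bmm fell by 1.14 (adjusted p = 0.0138) and the aspartate aminotransferase Got1 by 0.85 (adjusted p = 0.0196). ATP citrate lyase, ATPCL, fell by 0.87 (adjusted p = 0.0435) and the chaperone Hsp83 by 0.73 (adjusted p = 0.0216). Of these, hll and Hsp83 rose in GFP-negative flies against sucrose, by 2.32 and 0.95. In contrast, sug, a sugar-responsive regulator of lipid synthesis, rose by 1.29 (adjusted p = 0.0317). All 13 glycolysis genes were below 0, with 3 lower adjusted over the list alone, Hex-C at −0.73, Pgi at −0.64 and Gapdh2 at −0.53. Their median was −0.31 (camera adjusted p = 5.66e-06; adjusted p = 0.331 with an estimated correlation). Lipolysis had 2 of 19 above 0 and a median of −0.23 (camera adjusted p = 9.75e-06; adjusted p = 0.399 with an estimated correlation). Fat body markers lay on the same side, 4 of 17 above 0 with a median of −0.31 (camera adjusted p = 0.144), at −0.34 in thorax (percentile 0.1) and −0.29 in carcass (percentile 3.32). Trehalose and glycogen genes had a median of −0.35 (camera adjusted p = 0.00172; adjusted p = 0.331 with an estimated correlation). One-carbon genes had a median of −0.24 with Shmt at −0.54 and pug at −0.80 lower adjusted over the list alone (camera adjusted p = 0.0359; adjusted p = 0.655 with an estimated correlation).

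Camera called 10 further lists between the GFP groups, none of them with an estimated correlation. Lower medians were −0.42 for heat shock, −0.18 for the TCA cycle, −0.19 for oxidative phosphorylation, −0.28 for lipid synthesis and −0.22 for cytosolic ribosomal proteins (adjusted p = 0.569, 0.672, 0.71, 0.655 and 0.655 with an estimated correlation). The heat shock difference lay chiefly in carcass, with a median of −0.525 there and −0.012 in thorax (12 of 27 higher). Mitochondrial ribosomal proteins were at −0.13, muscle structure at −0.18 and haemocyte markers at −0.26 (adjusted p = 0.761, 0.676 and 0.655 with an estimated correlation). The Toll pathway at 0.27 and JAK/STAT at 0.42 were higher (adjusted p = 0.416 and 0.306 with an estimated correlation). In limma, 36 genes rose and 48 fell, but 0 passed in the 6 Dro-GFP libraries alone, and 16 without both Relish RNAi carcass libraries. The count was 47 without either control sucrose library, 35 without either Relish RNAi sucrose library, 55 without either Dro-GFP sucrose library, 24 and 13 without the GFP-negative thorax or carcass, and 46 and 12 without the GFP-positive thorax or carcass.

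Against Dro-GFP flies fed sucrose, GFP-positive flies raised genes of all 5 immune lists, and GFP-negative flies raised some of them. Heat shock genes lay above sucrose in both groups. In GFP-positive flies, edin rose by 8.13 ± 0.32 (adjusted p = 9.93e-05) and AttD by 6.77 ± 0.49 (adjusted p = 0.00105), and Rel by 1.53 (adjusted p = 0.00105). The JAK/STAT ligand upd2 rose by 3.08 (adjusted p = 0.0454) and its inhibitor Socs36E by 2.16 (adjusted p = 0.00442). The insulin receptor InR rose by 1.06 (adjusted p = 0.0223), while tobi fell by 2.50 ± 0.16 (adjusted p = 0.00105) and Pxn, a haemocyte peroxidasin, by 0.99 (adjusted p = 0.0371). All 13 antimicrobial peptides rose over all genes and adjusted over the list alone. So did 13 of 17 Toll effectors, or 15 adjusted over the list alone, 6 of 21 IMD pathway members, or 12, and 4 of 16 JAK/STAT genes, or 8. In that order of lists, adjusted p = 0.0407, 0.0407, 0.0199 and 0.0329 with an estimated correlation. The Toll pathway gave 4 of 18, or 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). The 184 genes higher and 62 lower became 1 in the 6 Dro-GFP libraries alone and 126 without both Relish RNAi carcass libraries. Single omissions gave 159 without either control sucrose, 140 without either Relish RNAi sucrose and 160 without either GFP-negative library, 103 and 38 without the Dro-GFP sucrose thorax or carcass, and 146 and 49 without the GFP-positive thorax or carcass.

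In GFP-negative flies, edin rose by 2.90 ± 0.32 (adjusted p = 0.0284), DptB by 2.61 ± 0.35 (adjusted p = 0.0436) and Rel by 1.09 (adjusted p = 0.0207). Nmdmc, a mitochondrial folate enzyme, rose by 2.21 ± 0.26 (adjusted p = 0.0382) and hll by 2.32 ± 0.23 (adjusted p = 0.0207). Heat shock genes gave 2 of 27 over all genes, Hsp83 at 0.95 (adjusted p = 0.0232) and Hsp67Bc at 1.15 (adjusted p = 0.0486). They gave 12 adjusted over the list alone, including Hsp23 at 2.82, Hsp27 at 2.79 and Hsp70Bb at 3.97, whose copies are near-identical (camera adjusted p = 1.29e-13; adjusted p = 0.0616 with an estimated correlation). Antimicrobial peptides gave 2 of 13, or 12 adjusted over the list alone (median 2.42; adjusted p = 0.0616 with an estimated correlation). One-carbon genes had 12 of 13 above 0 (camera adjusted p = 0.00011; adjusted p = 0.336 with an estimated correlation). The detoxification enzyme Cyp6a2 fell by 1.11 ± 0.13 (adjusted p = 0.0397). Both contrasts against sucrose were added after the values were seen. This one gave 23 genes higher and 3 lower. It gave 0 in the 6 Dro-GFP libraries alone, without both Relish RNAi carcass libraries, without the GFP-negative thorax or without the Dro-GFP sucrose carcass. The count was 4 without either control sucrose library, the Dro-GFP sucrose thorax or the GFP-negative carcass, 3 without either Relish RNAi sucrose library, 13 without either infected Relish RNAi library and 11 without either GFP-positive library.

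Library by library and without a replicate check, GFP-positive exceeded GFP-negative flies in the antimicrobial peptides by a median of 1.75 in thorax and 3.59 in carcass. In carcass, the chaperones Hsp70Bbb (−3.73), Hsp68 (−2.88) and Hsp26 (−2.80) were among the 10 lowest genes, beside Smvt, a multivitamin transporter (−3.26), and heat shock genes had a median of −0.53 (6 of 27 higher, percentile 0.0). In thorax, the storage protein Lsp2 (−4.22) and the odorant-binding Obp99b (−4.02) were the lowest apart from genes known only by a CG or CR number. CR11538 had nearly the same values as Lsp2 (−4.201), so their reads could be shared. Lipolysis had a median of −0.29 in thorax (3 of 19 higher). The GFP-negative thorax also held transcripts typical of carcass: the spermatheca gene Send1 was at 0.352 there, against −2.925 in the sucrose and −2.787 in the GFP-positive thorax, and CG43090, CG31681 and CG43074 shared this. Part of the difference between these thoraces in other genes thus cannot be assigned to GFP status. Compared with sucrose, heat shock genes had medians of 0.84 and 1.18 in GFP-negative thorax and carcass, both at percentile 100, and of 0.70 and 0.30 in the GFP-positive libraries. In carcass against sucrose, medians were −0.011 for both lipolysis and lipid synthesis in GFP-positive flies. In GFP-negative flies they were 0.239 for lipolysis, 0.173 for lipid synthesis, 0.227 for glycolysis and 0.203 for trehalose and glycogen. Ovary markers stood at −1.74 (1 of 21 higher) in the GFP-negative and −1.01 in the GFP-positive carcass against sucrose, the sucrose library being shared by both differences.

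The tissues themselves differed in most genes, with muscle genes higher in thorax and oenocyte, lipid and ribosomal genes higher in carcass. Camera did not call fat body markers between the tissues. Thoraces were higher in Act88F by 6.67 ± 0.47 (adjusted p = 7.87e-06) and in the flight muscle troponin TpnC4 by 6.33 ± 0.31 (adjusted p = 1.23e-06). Flightin, fln, was higher by 6.15 ± 0.32 (adjusted p = 1.61e-06), the sarcoplasmic calcium-binding protein Scp1 by 5.80 ± 0.08 (adjusted p = 6.36e-09) and Gad1, which makes GABA from glutamate, by 5.56 ± 0.11 (adjusted p = 2.57e-08). The noncoding CR45161 had nearly the same values as fln (6.15), so their reads could be shared. Carcasses were higher in the cuticle protein Cpr49Ab (−6.15 ± 0.14; adjusted p = 4.92e-08) and in Send1, a spermatheca endopeptidase (−4.82 ± 0.33; adjusted p = 6.95e-06). Of the muscle genes 25 of 27 were higher in thorax and 1 lower (median 2.31; camera adjusted p = 3.85e-11; adjusted p = 0.344 with an estimated correlation). Neuron markers gave 13 of 14 higher and 1 lower (median 2.97; camera adjusted p = 2.91e-06; adjusted p = 0.344 with an estimated correlation). Oxidative phosphorylation gave 30 of 36 higher and 2 lower (median 0.80; camera adjusted p = 2.1e-06; adjusted p = 0.65 with an estimated correlation). Mitochondrial ribosomal proteins gave 39 higher and 8 lower (40 and 8 adjusted over the list alone; adjusted p = 0.816 with an estimated correlation). JNK genes gave 7 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation).

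Carcasses were higher in fat and protein synthesis. Relative to carcass, 0 of 9 oenocyte markers were higher and 9 lower in thorax (median −2.53), and 2 and 16 of 20 lipid synthesis genes (median −1.26). The same held for 1 and 17 of 19 lipolysis genes (median −0.80; camera adjusted p = 1.96e-06) and 2 and 83 of 90 cytosolic ribosomal proteins (median −0.89; camera adjusted p = 1.83e-22). For the ribosomal proteins adjusted p = 0.411 with an estimated correlation, and for the other lists adjusted p = 0.344. Immune genes lay lower in thorax as well. Of Toll effectors, 0 of 17 were higher and 15 lower, of IMD pathway members 1 and 13 of 21, and of Toll pathway members 4 and 12 of 18 (adjusted p = 0.345, 0.344 and 0.588 with an estimated correlation). Proteasome genes gave 1 and 18 of 27 and one-carbon genes 1 and 7 of 13 (adjusted p = 0.663 and 0.65 with an estimated correlation). Adjusted over the list alone, counts of the lists in this comparison were the same except where given and for the TCA cycle (11 and 6), haemocyte (8 and 5) and gut markers (3 and 1). Camera did not call the antimicrobial peptides (0 higher and 3 lower; 0 and 2 adjusted over the list alone), JAK/STAT (6 and 6), heat shock (12 and 6), glutamate metabolism (7 and 6), the TCA cycle (10 and 6), glycolysis (4 and 6), trehalose and glycogen (4 and 5) or lipoproteins (3 and 4). Nor did it call insulin signalling (3 and 3), fat body (2 and 6), haemocyte (7 and 5), gut (3 and 2), ovary (1 and 4) or Malpighian tubule markers (3 and 4). In limma, 4177 genes were higher and 3507 lower in thorax over 7 pairs of libraries, and 4725 passed in the 3 sucrose pairs alone.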

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

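Every test of an explanation in this part, and every count of other splits of the libraries, was chosen after the result was seen, except the comparison of Gdh with muscle and mitochondrial genes; the limits set for the tests on flight muscle and on single samples were rewritten once their values were known.

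The infection differences of muscle structure genes had opposite directions in control and Relish RNAi flies, in both tissues, with a median difference between the lines of 0.627 that did not pass with an estimated correlation. Act88F had opposite directions in the thoraces of these lines, 1.073 apart. Gdh did so in both tissues, 1.511 apart in thorax and 0.251 in carcass. The differences of Act88F and Gdh between single libraries of a tissue were not tested.

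Eggshell transcripts were high in the carcasses of Relish RNAi flies, some of them on sucrose only. The 7 genes called in carcass were higher than in control flies on both feeds. Vm26Ac, however, stood at 6.767 on sucrose and −0.495 on infection, and the ovary list mean at 2.115 and 0.97. If Relish knockdown in flight muscle had raised the 7 genes in muscle, they would differ in thorax too. There their median was 0.421, with values from −0.291 to 0.911, against 1.142 or more for each in carcass (median 2.688). The 7 genes were picked for their carcass difference, and the limit was set after the values were seen, so this comparison cannot decide the question. An earlier limit for this test, a thorax median under 10% of the carcass median, had not been met. RNA from ovary remnants is a candidate explanation: the 7 germline markers outside the called genes had a median difference of 1.69, all 7 above 0, from 0.026 to 2.621. An effect of the line on egg production stays open and was not tested.

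The antimicrobial peptides were induced less in Relish RNAi than in control flies, called by camera (adjusted p = 1.03e-07) but not with an estimated correlation (adjusted p = 0.524) nor for any gene over all genes. Part of this lay in sucrose, where the list means were higher in Relish RNAi flies, −2.475 against −2.911 in thorax and −2.437 against −2.935 in carcass, beside 1.036 against 1.669 and 1.928 against 2.639 on infection. A knockdown acting within flight muscle alone would leave the carcass alike in both lines, yet the carcass median was −1.42 with 11 of 13 peptides below 0, beside −1.055 and 12 of 13 in thorax. A weaker infection of the Relish RNAi flies would lower Toll effectors as well; their median was −0.807 with 17 of 17 below 0 in carcass, but −0.003 with 9 of 17 below 0 in thorax. Neither explanation can be told apart from a difference between single samples, since each condition had 1 library per tissue.

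Gdh was high in the infected Relish RNAi thorax. A larger share of muscle and mitochondrial RNA in that library would raise other such genes as much, and 0 of 81 genes of oxidative phosphorylation, the TCA cycle and muscle structure reached its difference, the largest being 1.315 (TpnC47D) and the median 0.485 (SD 0.229), which argues against this share as the whole cause. However, 78 of the 81 were above 0, so such a share may account for part of it. A difference between single samples unrelated to Relish cannot be told apart from an effect of the knockdown. Gdh included, 32 genes of the table, 0.24%, had a difference at least as high. Genes that differed as much in the other direction were not counted, so the share of all such differences is not known. No second library of any condition was available.

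Other splits of the libraries were counted for the comparisons with at least 3 libraries a group. For infection in thorax, 3 of 34 splits gave as many genes at an unadjusted p under 0.05 as the real 830, the highest of the others 1068. For infection in carcass, 9 of 34 did (real 1702, highest other 2050), and for the difference of the tissues 60 of 100 drawn (real 651, highest other 1896). That highest split, at several times the real count, points to a structure of the samples, which was not identified or tested. For infection over both tissues, with weights by least squares, 5 of 34 splits passed as many genes as the real 227, the highest other 330. Chance was not excluded for these counts. For thorax against carcass, 1 of 64 splits, the real one, gave 7684 genes and the highest other 0, so chance was excluded.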

How the results depend on the processing

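The fits on libraries without both Relish RNAi carcasses, the filter on a range of at least 0.5 and random lists without matching were chosen after the values were seen, as were the 6 added contrasts; the other alternatives were planned. Unknown depth limits every value, since genes with few reads cannot be told from genes that did not vary. No paired analysis was possible because every group holds 1 library only; the tissues were matched by condition in the model with a tissue term. The planned pseudocounts, filters on low values and mean trend were not run, because the deposited values are centred logs, and Relish RNAi in carcass could not be estimated without its libraries. Median-of-ratios scaling shifted the libraries by values from −0.0246 (Relish RNAi sucrose carcass) to 0.0171. All 280 list medians moved by less than the SD of the differences of their members. That limit is wide, so the sign of list medians near 0 is not settled by it. Without matching, 245 percentiles stayed alike and 35 moved. No named gene changed sign: over all alternatives, 954 values of 62 genes kept their call for infection over both tissues and 286 lost it, and 411 of 32 genes kept it and 261 lost it for GFP-positive against GFP-negative flies. For thorax against carcass, all 460 values of 20 genes kept it.

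Counts of genes that moved by over 1.5 times were as follows, and the cause was not tested except where fewer libraries or another threshold show it. With quantile normalization, infection in carcass gave 2 (0 before), Relish RNAi in carcass 4 (7 before) and infection in the Relish RNAi line 11 (32 before). At a threshold of 0.1, infection in carcass gave 65, GFP-positive against GFP-negative 164 and GFP-positive against sucrose 447. With the filter on range, infection in carcass gave 28, and without the line term 24. With fewer libraries, Relish RNAi gave 0 in thorax and 0 in carcass, both from 1 tissue alone and without the Dro-GFP libraries. In the 6 Dro-GFP libraries alone, GFP-positive against GFP-negative gave 0, GFP-positive against sucrose 1 and GFP-negative against sucrose 0. The 3 sucrose pairs gave 4725 for thorax against carcass. Without both Relish RNAi carcasses, the counts were 16 for GFP-positive against GFP-negative, 90 for infection over both tissues, 29 for the control line, 0 for the Relish RNAi line, 126 and 0 for GFP-positive and GFP-negative against sucrose, and 1 for Relish RNAi over both tissues.

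With each library left out in turn, counts ran from 0 to 0 for infection in thorax and for the difference of the tissues, from 0 to 169 for infection in carcass, from 0 to 8 for Relish RNAi in thorax and from 1 to 75 in carcass. They ran from 12 to 76 for GFP-positive against GFP-negative, from 0 to 10 for the difference of infection between the lines and from 7018 to 7405 for thorax against carcass. For the added contrasts, they ran from 103 to 216 for infection over both tissues, from 24 to 63 in the control line and from 0 to 90 in the Relish RNAi line. For GFP-positive and GFP-negative flies against sucrose the ranges were 38 to 228 and 0 to 19, and for Relish RNAi over both tissues 0 to 10. In these fits a lone library of a group is assumed to vary like the others.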

Other observations

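The genes of this part were chosen after their values were seen. Infection over both tissues also raised genes outside the fixed lists. A set of 3 genes of catecholamine metabolism, with no list of the path tested, rose: ple, tyrosine hydroxylase, by 1.58 ± 0.20 (adjusted p = 0.00897), e, which joins dopamine to beta-alanine, by 1.31 ± 0.23 (adjusted p = 0.0383), and Pu, which starts the synthesis of the pterin cofactor of ple, by 0.78 ± 0.14 (adjusted p = 0.0378), each in 8 of 8 infected libraries against their sucrose library. Other immune-induced genes rose too, SPH93, a serine protease homologue, by 2.87 ± 0.32 (adjusted p = 0.00427), GNBP-like3 by 2.63 ± 0.14 (adjusted p = 0.000104) and Listericin, an antibacterial peptide, by 2.24 ± 0.21 (adjusted p = 0.00163). The zinc transporter family gene Zip89B rose by 1.64 ± 0.13 (adjusted p = 0.000717) and Xrp1, a stress-induced transcription factor, by 0.68 ± 0.07 (adjusted p = 0.00414). Among genes that fell were Jhe, juvenile hormone esterase, by 0.60 ± 0.10 (adjusted p = 0.0321), Indy, a citrate transporter, by 0.27 ± 0.05 (adjusted p = 0.0386), and Prat2, of purine synthesis, by 0.68 ± 0.11 (adjusted p = 0.0227), the last 2 in 6 of 8 libraries.

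Single genes set libraries apart, as values without a replicate check. Smvt, the multivitamin transporter, stood in carcass at 0.56 in control sucrose and 1.76 in infected control, at 2.50 in Relish RNAi sucrose and 5.59 in infected Relish RNAi, and at −1.36, 2.07 and −1.18 in Dro-GFP sucrose, GFP-negative and GFP-positive flies. Uro, urate oxidase of the Malpighian tubule, was at −2.17 in Dro-GFP sucrose carcass and at 2.59 and 2.86 in the infected ones. Flight muscle transcripts were lower in Dro-GFP thoraces than in those of the Act88F-Gal4 lines: Act88F was at 1.66 to 2.00 against 4.01 to 4.90. In thorax, the storage protein Lsp2 was at 4.22 in Dro-GFP sucrose and 4.79 in GFP-negative flies, but at 0.57 in GFP-positive flies, and the alpha-glucosidase tobi at 1.49, 2.03 and −0.66 in that order. The cytokine gene upd3 was at 1.37 to 1.64 in the 4 thoraces of the Act88F-Gal4 lines and at −1.21 in the Dro-GFP sucrose thorax. The photoreceptor genes ninaE and Arr2 were −2.77 and −2.53 apart between the GFP-negative and sucrose thoraces. The germline gene nos was at 3.33 in the Dro-GFP sucrose carcass and at −0.61 and −0.29 in the infected ones.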
